A study of Mus musculus with 24 samples.

How the data were processed

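Tregs and B cells were sorted from tumours and draining lymph nodes of mice carrying B16-F0 melanoma, and RNA was extracted with TRIzol and made into stranded mRNA libraries, per the labels. The authors deposited 1 table of read counts per gene for 56791 genes and 24 libraries, which is the only processed file used. The deposited values are raw counts without normalization, and the deposited table also gives each gene's exon length in bases. The table's 24 sample columns were matched to the labels by name, with 0 columns unmatched and 0 blank values. Per the submitters' processing notes, reads were trimmed with fastp 0.23.4, aligned with STAR 2.5.3a and counted with featureCounts. The notes name the builds GRCh38 and GRCm39; the coordinates in the deposited table lie on mouse chromosomes and are given here as GRCm39. The annotation release, the strand setting and the handling of duplicate or multiply aligned reads are not given in the sources used here. Between 69.7 and 75.8 % of the counts from 1 to 10 were even numbers, as when both mates of a read pair are counted, so a count is not always 1 independent fragment. Bounds from a floor of counts, below, cover counting error only.

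Depth ran from 6245822 to 16239055 counts per library, and mitochondrial genes took 0.391 to 0.924 % of counts. That share was lower in the libraries labelled KO than WT in each comparison, at 0.420 ± 0.0249 and 0.689 ± 0.0406 % in tumour Tregs, 0.669 ± 0.0266 and 0.782 ± 0.0376 % in lymph node Tregs, 0.675 ± 0.0495 and 0.819 ± 0.0378 % in tumour B cells, and 0.785 ± 0.0578 and 0.894 ± 0.0273 % in lymph node B cells (SD, n = 3). Between replicates of a group the chi-square per gene, which is near 1 for counting error of single reads and near 2 where both mates are counted, ran from 2.43 to 11.5 with a median of 3.55, and was highest in pairs with tumour B cell KO replicate 1 or WT replicate 2. For genes with 40 to 200 reads over a pair it ran from 2.23 to 5.00 with a median of 2.60. Most pairs thus differed little beyond counting error at such depth, and whether replicates are repeats of 1 sample was not tested. The 8 groups of 3 libraries were taken from the labels for cell type, tissue and genotype. The comparisons, their tests, gene lists, rule for named genes and all but 3 of the alternatives were chosen before the data were examined. The other 3 are named in the closing sections, as are further tests and counts chosen after results had been seen.

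Pairwise comparisons (KO against WT labels in each cell type and tissue, and tumour against lymph node in each cell type labelled WT) were fitted on the 6 libraries concerned, and an interaction of genotype label with tissue on the 12 libraries of each cell type. Each used edgeR 4.0.16 in R 4.3.3 with TMM scaling, the package's own filter on low counts and the quasi-likelihood F test (two-sided), and called a gene at an adjusted p under 0.05. Every adjusted p in the text is a Benjamini-Hochberg value, for genes over all genes tested in a comparison. Levels are given as CPM, counts scaled to the effective library total (by TMM over the libraries of each comparison or, for Appl2 levels, figures, the shares of other lymphocytes and levels given outside a comparison, over all 24), with the SD over 3 libraries, and log2 fold changes with the standard error from the fit. A gene with 0 reads in a group is given as a bound from a floor of 3 counts over the group. The design has no block, since the labels do not say what a replicate number marks.

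Before the data were examined, 37 gene lists were fixed for pathways, cell states and markers of other cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the data. At the preset value 18 lists passed in tumour Tregs, 14 in lymph node Tregs, 17 in tumour B cells, 10 in lymph node B cells, 15 and 16 in the tissue comparisons of Tregs and B cells, and 16 and 12 in their interactions. With the estimated correlation 9, 8, 13, 6, 10, 11, 9 and 10 of these passed. That second test also takes its degrees of freedom from the few libraries of the fit, so a lost call need not reflect correlation between members. In the text the values of that second test stand mainly beside lists that lost their call. Beside each list stand the number of members that passed over all genes and the number adjusted over the list alone. The genes named are Appl2, Foxp3 in Tregs, the 10 largest changes in each direction among called genes with a mean of at least 5 CPM and groups that did not overlap, and up to 4 members of each list with the smallest p. In the interactions the 5 largest in each direction were named. Groups of 3 against 3 fail to overlap by chance for 10 % of unchanged genes. Genes on that list whose value rested on 1 library are given with the value without it or not named.

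The fit was tested on simulated counts with the observed means and spread, in which 100 genes were changed by each fold, drawn from genes above a minimum mean count. Far more genes passed in the real comparisons, so the rates hold for the simulated setting alone. In tumour Tregs it recovered 57 % of genes changed 1.5-fold and 85 % of those changed 2-fold, with 6 false calls among 148. In lymph node Tregs these were 65 and 82 % (4 false of 151), in tumour B cells 30 and 74 % (10 of 114) and in lymph node B cells 62 and 86 % (7 of 155). For the tissue comparisons they were 72 and 83 % in Tregs (9 of 164) and 52 and 73 % in B cells (11 of 136), and for the interactions 43 and 68 % in Tregs (5 of 116) and 26 and 58 % in B cells (9 of 93).

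The share of other lymphocytes' RNA was estimated as the ratio of marker levels to those in the other sorted cell of the same tissue and genotype label. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a filter at 5 CPM in 3 libraries, all 4 groups of a cell type in 1 fit, the replicate number as a block, and leaving out each library in turn. Other splits of the libraries were also counted. No library was left out of the values reported. Values of some genes selected or listed as above are not reported here.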

Results

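Gene expression was measured by bulk RNA sequencing in regulatory T cells (Tregs, the suppressive CD4 T cells that express the transcription factor Foxp3) and in B cells, sorted from tumours or draining lymph nodes of mice bearing B16-F0 tumours, a pigmented mouse melanoma line. The mice were labelled Foxp3-Cre, which express Cre recombinase under control of the Foxp3 gene (WT), or Foxp3-Cre Appl2 f/f (KO), in which that recombinase is meant to remove loxP-flanked exons of Appl2. Appl2 codes for an adaptor protein of early endosomes that binds the small GTPase Rab5 and several receptors. The 24 libraries formed 8 groups of 3, one for each combination of cell type, tissue and genotype label. Total reads ran from 6245822 to 16239055 per library, and between 18025 and 21217 genes had at least 1 read. The labels do not say whether the 3 libraries of a group came from separate animals or are repeats of 1 sample. The p-values below therefore measure the spread between these libraries and no more, and that spread was small. Every "higher", "lower", "rose" and "fell" below is libraries labelled KO relative to libraries labelled WT, or tumour relative to lymph node, and changes are log2 fold changes with their standard error. Levels in CPM are scaled over the libraries of the comparison they stand in, so a group's level differs between comparisons, and those of Appl2 in the next paragraph and in the figures are scaled over all 24 libraries. Counts of list members that rose or fell are over all genes tested; adjusted over the list alone they were the same, except where the second count follows in parentheses.

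The first question was whether Appl2 itself followed the genotype labels. Appl2 lies on chromosome 10 at 83435897 to 83484602 of GRCm39, on the minus strand, and no other annotated gene overlaps its exons. In tumour Tregs it averaged 24.6 ± 3.16 CPM (SD, n = 3) in the libraries labelled KO and 53.7 ± 4.25 CPM in those labelled WT, a change of -1.12 ± 0.10 (edgeR quasi-likelihood test, adjusted p = 5.5e-12). In tumour B cells the levels were 15.5 ± 3.05 and 44.8 ± 6.13 CPM, a change of -1.53 ± 0.16 (edgeR, adjusted p = 5.8e-06). In lymph node B cells they were 11.3 ± 0.424 and 24.1 ± 2.65 CPM, a change of -1.08 ± 0.13 (edgeR, adjusted p = 2.2e-07). Lymph node Tregs went against the label, with 26.2 ± 3.02 CPM in the libraries labelled KO and 22.2 ± 3.80 CPM in those labelled WT, a difference of 0.23 ± 0.12 that did not pass (edgeR, adjusted p = 0.159). Without lymph node Treg WT replicate 1 that difference was 0.36 and passed as higher (edgeR, adjusted p = 0.0201, against a range up to 0.537 over the alternatives tried). The KO effect on Appl2 differed between tumour and lymph node in Tregs by -1.36 ± 0.16 (edgeR interaction term, adjusted p = 6.5e-09), whereas in B cells the difference of -0.45 ± 0.21 did not pass (edgeR, adjusted p = 0.14). The counts are gene totals with no exon resolution, so they cannot show whether the flanked exons were removed.

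**Figure D1:**
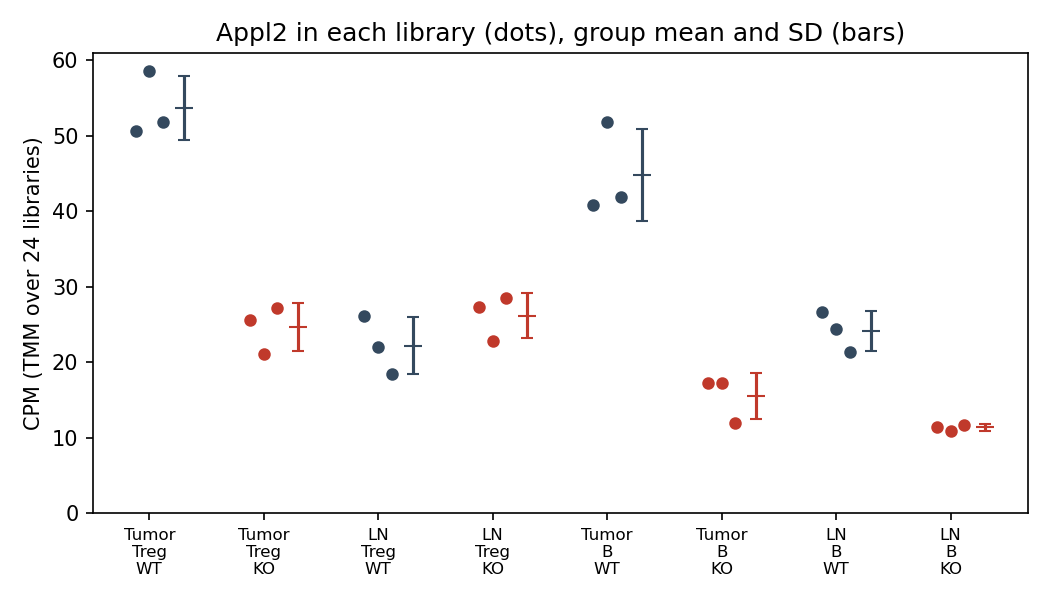
Appl2 in CPM (linear axis from 0) for each of the 24 libraries, by cell type, tissue and genotype label, with each group's mean and SD (n = 3). The libraries labelled KO sit below those labelled WT in both B cell pairs and in tumour Tregs, while the lymph node Treg groups average 26.2 (KO) and 22.2 (WT) CPM.

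Tregs of the tumour were compared between genotype labels to ask what the deletion changes in tumour-infiltrating Tregs. Foxp3, the lineage transcription factor, was lower in the libraries labelled KO at 289 ± 6.85 against 468 ± 18.4 CPM (SD, n = 3), a change of -0.70 ± 0.05 (edgeR, adjusted p = 1.5e-15). The gene lies on chromosome X at 7439883 to 7461484 of GRCm39. Ppp1r3f, Ccdc22, Gm36995 and Flicr also cover 31.5 % of its exon bases, and the strand setting of the counting is not stated, so its level is uncertain to that extent. Ikzf2 (Helios, a transcription factor of stable Tregs) fell from 497 ± 5.71 to 241 ± 11.9 CPM, a change of -1.04 ± 0.05, and Il2ra, the interleukin 2 receptor alpha chain, changed by -0.74 ± 0.05. Fosb, a subunit of the AP-1 transcription factor, rose from 58.7 ± 4.94 to 972 ± 41.3 CPM, a change of 4.05 ± 0.06 (edgeR, adjusted p = 5.0e-37). Mki67, a marker of cycling cells, fell from 1834 ± 10.3 to 517 ± 21.3 CPM, a change of -1.83 ± 0.04. In all, 7869 of 14442 genes tested passed, 3944 higher and 3925 lower (3591 and 4339 with upper-quartile scaling), of which 1213 rose and 1375 fell at least 2-fold.

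By the gene lists, 24 of 25 immediate early genes, which respond within minutes to stimulation or stress, rose in tumour Tregs labelled KO, with a median of 1.68 (camera, adjusted p = 6.65e-75). Among them Klf4 changed by 3.92 ± 0.09, Atf3 by 3.75 ± 0.08 and Ppp1r15a by 1.56 ± 0.04. The TNF and NF-kB list had 18 of 19 members higher, including Tnip1 at 1.48 ± 0.04 and Gadd45b at 1.78 ± 0.06 (camera, adjusted p = 8.21e-16). Heat shock genes, which also mark stress during tissue dissociation, were higher for 10 of 11 members over all genes and 11 adjusted over the list alone, with Hsph1 at 1.36 ± 0.05 (camera, adjusted p = 1.41e-15). The heat shock genes took 3.43 ± 0.0144 % of reads in the libraries labelled KO and 2.18 ± 0.0300 % in those labelled WT (SD, n = 3). Cell cycle genes fell for 27 of 33 members and rose for 3, with a median of -0.77, Cenpf at -2.39 ± 0.06 and Top2a at -1.08 ± 0.04 (camera, adjusted p = 9.66e-14). In the TGF-beta list 8 of 14 members rose and 3 fell, with Skil at 1.27 ± 0.05 and Tgif1 at 1.46 ± 0.06 (camera, adjusted p = 0.000249). With an estimated correlation the adjusted p by camera was 0.00162 for immediate early and 0.0066 for TNF and NF-kB genes. It was 0.0066 for cell cycle and 0.045 for TGF-beta genes.

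The lists of Treg programmes passed at the preset inter-gene correlation and not in the test with an estimated one. The estimates were -0.049 for Treg identity, 0.0041 for effector Treg and -0.015 for naive and central T cell genes. These lie below the preset 0.01, so a higher correlation between members does not account for the loss in these lists. The second test also has fewer degrees of freedom, which by itself gives larger p-values. Of 15 Treg identity genes 11 fell and 1 rose (camera, adjusted p = 0.000852, and adjusted p = 0.0547 with an estimated correlation). Effector Treg genes fell for 15 and rose for 6 of 25 (16 and 6 adjusted over the list alone; camera, adjusted p = 0.00261, and adjusted p = 0.0687 with an estimated correlation). Areg, a tissue repair growth factor, changed by -1.47 ± 0.05, the suppressive mediator Fgl2 by -1.43 ± 0.05 and granzyme B (Gzmb) by -1.30 ± 0.05, while Irf4, a transcription factor of effector Tregs, rose by 2.47 ± 0.07. Tcf7, a transcription factor of naive and memory T cells, rose by 1.76 ± 0.07 and the homing regulator Klf2 by 1.29 ± 0.10, while the cytokine receptor Il7r changed by -1.41 ± 0.05. Naive and central T cell genes rose for 11 and fell for 3 of 14 (camera, adjusted p = 0.00559, and adjusted p = 0.0821 with an estimated correlation). Helper T cell genes rose for 14 and fell for 3 of 21 (14 and 4 adjusted over the list alone; camera, adjusted p = 0.00386, and adjusted p = 0.174 with an estimated correlation). Among them the cytokine Tnf was at 2.57 ± 0.14 and Tbx21, the regulator of type 1 helper cells, at 1.59 ± 0.10. Glycolysis genes fell for 12 and rose for 2 of 17 (camera, adjusted p = 0.000441, and adjusted p = 0.235 with an estimated correlation). Integrated stress response genes such as Atf4, at 1.77 ± 0.05, rose for 11 and fell for 1 of 18 (camera, adjusted p = 8.7e-05, and adjusted p = 0.144 with an estimated correlation).

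Transcripts of other cells moved alongside these groups. All 11 melanoma markers fell, with a median of -6.20 whether or not Oca2, which had 0 reads in a group, is set at its bound (camera, adjusted p = 4.5e-48). Dct, a melanin synthesis enzyme, was at 2388 ± 92.7 CPM in the libraries labelled WT and 37.0 ± 2.30 CPM in those labelled KO, and Tyrp1 at 189 ± 7.50 and 1.65 ± 0.368 CPM. Whether less melanoma RNA adds to the fall of glycolysis genes in the libraries labelled KO was not tested. All 11 B cell markers rose, with a median of 3.49 and Pax5 at 4.35 ± 0.30 (camera, adjusted p = 1.03e-06). Among the largest increases were the immunoglobulin genes Ighg2c, from 1.70 ± 0.875 to 452 ± 11.8 CPM, and Igkc, from 28.7 ± 3.03 to 498 ± 11.8 CPM. Reads of closely related constant region or H2 genes are hard to assign to 1 copy. MHC class II genes rose for 10 of 12, with H2-Ab1 at 678 ± 21.1 against 137 ± 8.49 CPM (camera, adjusted p = 7.1e-10, and adjusted p = 0.0428 with an estimated correlation). All 12 CD8 T and NK cell markers rose, with Cd8b1 from 15.7 ± 1.45 to 103 ± 4.26 CPM (camera, adjusted p = 8.03e-10). Scaled over all 24 libraries, Cd4 fell from 678 ± 17.0 to 492 ± 8.74 CPM. The general T cell gene Cd3e stayed near level on that scale, at 216 ± 6.58 (WT) and 211 ± 4.72 CPM (KO). How far other T cells in the gate labelled KO add to the changes of Foxp3, Treg identity and helper T cell genes was not tested. Dendritic cell markers rose for 7 and fell for 1 of 8 (camera, adjusted p = 0.031, and adjusted p = 0.287 with an estimated correlation).

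**Figure D2:**
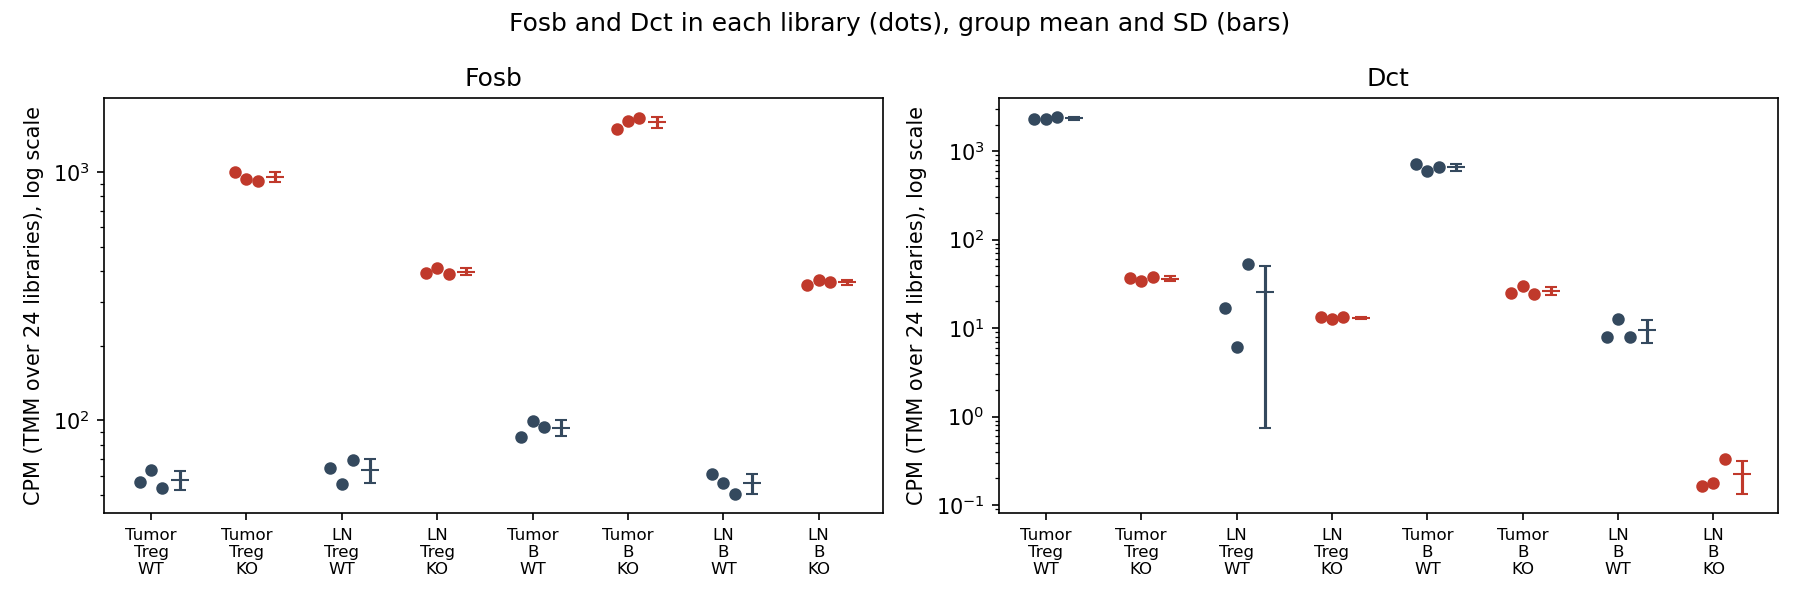
Fosb and Dct in CPM (log axis) for each library, by cell type, tissue and genotype label, with group means and SD (n = 3). Fosb is higher in the libraries labelled KO in every cell type and tissue, and Dct reaches 2345 CPM in tumour Tregs labelled WT against 36.3 CPM in those labelled KO.

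Lymph node Tregs were compared in the same way; since Appl2 was not lower in the libraries labelled KO, each direction here follows the labels alone. Fosb rose from 65.0 ± 7.52 to 406 ± 15.6 CPM (SD, n = 3), a change of 2.64 ± 0.06 (edgeR, adjusted p = 3.6e-23), and the orphan nuclear receptor Nr4a2 by 2.29 ± 0.07. Ctla4, an inhibitory receptor central to Treg suppression, rose from 915 ± 38.7 to 1404 ± 46.4 CPM, a change of 0.62 ± 0.04, while Foxp3 differed by -0.06 ± 0.04 and did not pass (edgeR, adjusted p = 0.342). Irf4 changed by 1.09 ± 0.06, Pdcd1, which codes for PD-1, by -0.92 ± 0.08 and Gzmb by -0.87 ± 0.07. Of 14613 genes tested 3689 passed, 2010 higher and 1679 lower (1808 and 2105 with upper-quartile scaling), with 540 up and 323 down at least 2-fold.

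Immediate early genes rose for 24 and fell for 1 of 25 in lymph node Tregs labelled KO, with a median of 1.09 (camera, adjusted p = 1.88e-107). Heat shock genes rose for 10 of 11, with Hsph1 at 1.36 ± 0.04 (camera, adjusted p = 1.58e-37), and took 3.31 ± 0.0105 % of reads against 2.21 ± 0.0159 % (SD, n = 3). The TNF and NF-kB list rose for 16 of 18, with Tnfaip3, an inhibitor of NF-kB signalling, at 0.85 ± 0.04 (camera, adjusted p = 6.24e-17). Cholesterol and fatty acid synthesis genes rose for 12 of 22 (14 adjusted over the list alone), with the desaturase Scd1 at 2.87 ± 0.10, Insig1 at 1.52 ± 0.12 and Hmgcs1 at 0.83 ± 0.10 (camera, adjusted p = 1.59e-06). Type I interferon response genes fell for 12 and rose for 1 of 24 (14 and 1 adjusted over the list alone), with Xaf1 at -1.21 ± 0.09 and Ifit3 at -0.97 ± 0.08 (camera, adjusted p = 5.2e-05). Effector Treg genes fell for 12 and rose for 3 of 25 (13 and 3 adjusted over the list alone; camera, adjusted p = 0.00542, and adjusted p = 0.07 with an estimated correlation). B cell markers rose beside them for 13 of 14 (camera, adjusted p = 2.21e-37). So did 11 of 12 MHC class II genes, with H2-Ab1 from 102 ± 3.17 to 648 ± 13.0 CPM (camera, adjusted p = 1.51e-60). Scaled by 14 markers, B cell RNA amounted to 5.22 ± 0.288 % of the libraries labelled KO and 0.940 ± 0.0450 % of those labelled WT. Stromal and endothelial markers fell for 10 of 11, with Col4a1 from 90.4 ± 6.84 to 4.48 ± 1.08 CPM (camera, adjusted p = 7.89e-27). Macrophage and monocyte markers rose for 2 of 9 (3 adjusted over the list alone), with Lyz2 at 1.68 ± 0.08 (camera, adjusted p = 0.000867, and adjusted p = 0.07 with an estimated correlation). Glycam1, a mucin of high endothelial venules, went from 29.4 ± 5.65 to 0.187 ± 0.0555 CPM.

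B cells of the tumour were compared to ask whether the Treg-directed deletion was accompanied by changes in another cell type. Scaled over all 24 libraries, Foxp3 was read at 8.17 ± 1.94 and 10.3 ± 2.64 CPM in tumour B cells labelled KO and WT and at 7.96 ± 0.324 and 10.9 ± 1.502 CPM in those of lymph node (SD, n = 3), reads whose origin was not tested. Fosb rose from 91.9 ± 8.54 to 1561 ± 94.8 CPM (SD, n = 3), a change of 4.09 ± 0.09 (edgeR, adjusted p = 1.3e-12). Irf4, which B cells raise on activation and on the way to plasma cells, rose from 97.2 ± 3.84 to 494 ± 23.9 CPM, a change of 2.35 ± 0.08. Igha, the constant region of IgA, fell from 731 ± 66.2 to 166 ± 17.4 CPM, a change of -2.14 ± 0.09, and Jchain, the joining chain of secreted IgA and IgM, changed by -1.25 ± 0.11. Mki67 rose from 154 ± 3.73 to 431 ± 62.2 CPM, a change of 1.49 ± 0.10. Of 13483 genes tested 5410 passed, 2871 higher and 2539 lower (2482 and 3053 with upper-quartile scaling), with 902 up and 998 down at least 2-fold. Tumour B cell KO replicate 1 and WT replicate 2 stood apart from the other 2 libraries of their groups, with a chi-square per gene of 10.7 to 11.5 and 7.89 to 8.47 against 3.49 and 3.10 between the others. Without both, 5748 genes passed.

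Among the lists in tumour B cells, B cell activation genes rose for 14 and fell for 1 of 20 (15 and 1 adjusted over the list alone), with Tnfaip3 at 2.53 ± 0.08, Nr4a1 at 2.17 ± 0.07 and the NF-kB subunit Rel at 2.04 ± 0.07 (camera, adjusted p = 7.34e-16). Germinal centre genes rose for 8 of 13, with Bcl6, the master regulator of germinal centre B cells, at 1.16 ± 0.11 and Nuggc at 2.11 ± 0.14 (camera, adjusted p = 2.56e-05). Cell cycle genes rose for 26 of 33 (27 adjusted over the list alone), with Pcna at 1.72 ± 0.10 and Top2a at 1.74 ± 0.12 (camera, adjusted p = 4.43e-10). Immediate early genes rose for 21 of 25 (22 adjusted over the list alone), with Klf4 at 3.73 ± 0.09 and Nr4a3 at 3.57 ± 0.11 (camera, adjusted p = 1.86e-55). The TNF and NF-kB list rose for 13 and fell for 1 of 19 (14 and 1 adjusted over the list alone), with Gadd45b at 3.16 ± 0.11 (camera, adjusted p = 8.51e-13). Integrated stress response genes rose for 11 and fell for 2 of 17 (12 and 2 adjusted over the list alone), with Ddit3 at 2.31 ± 0.09 (camera, adjusted p = 3.51e-05). Heat shock genes rose for 10 of 11, with Hsp90aa1 at 1.86 ± 0.07 (camera, adjusted p = 5.13e-26). They took 4.54 ± 0.0781 % of reads against 2.24 ± 0.0303 % (SD, n = 3). The plasma cell list split, with 8 members higher and 3 lower of 21, and did not pass (camera, adjusted p = 0.193). The TGF-beta list rose for 5 and fell for 2 of 13 (6 and 2 adjusted over the list alone; camera, adjusted p = 0.00438, and adjusted p = 0.0648 with an estimated correlation).

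Other cells' transcripts moved in tumour B cells too. T cell markers rose for 13 of 16, with Thy1 at 3.26 ± 0.19 (camera, adjusted p = 1.12e-10). Scaled by 15 markers, T cell RNA amounted to 5.28 ± 0.398 % of the libraries labelled KO and 0.670 ± 0.180 % of those labelled WT. That scale takes tumour Tregs as the T cell reference. Over all 24 libraries, Cd4 was at 1.09 ± 0.786 (KO) and 1.11 ± 0.703 CPM (WT), while Cd3e was at 9.56 ± 1.57 and 1.03 ± 0.298 CPM. T cell RNA that rose without Cd4 need not match the Treg profile, so these shares and counts drawn from them are approximate. All 8 CD8 T and NK cell markers rose, with Cd8b1 from 0.540 ± 0.114 to 17.4 ± 1.71 CPM and a median of 3.54, or 3.41 with Gzmk at its bound (camera, adjusted p = 1.98e-06). Macrophage and monocyte markers fell for 11 of 12, with Lyz2 from 93.1 ± 6.65 to 20.2 ± 1.31 CPM (camera, adjusted p = 4.72e-08). All 9 melanoma markers fell, with Dct from 648 ± 45.7 to 25.9 ± 2.92 CPM (camera, adjusted p = 3.87e-20). Stromal markers fell for 5 of 6 (camera, adjusted p = 2.26e-06). Erythroid and platelet markers fell for 5 of 7, with the haem synthesis enzyme Alas2 at -2.08 ± 0.14 (camera, adjusted p = 2.26e-06).

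In lymph node B cells the clearest group was again the immediate early genes, all 24 of which rose, with a median of 1.41 (camera, adjusted p = 1.69e-174). Fosb rose from 54.6 ± 4.96 to 352 ± 6.81 CPM (SD, n = 3; edgeR, adjusted p = 1.6e-23). Fos rose from 84.4 ± 3.31 to 507 ± 26.6 CPM and Junb from 132 ± 5.89 to 620.2 ± 5.05 CPM. B cell activation genes rose for 13 and fell for 1 of 17 (13 and 2 adjusted over the list alone), with Nr4a1 at 1.24 ± 0.05, Cd69 at 1.03 ± 0.06 and Egr3 at 1.14 ± 0.06 (camera, adjusted p = 1.67e-16). The immunoglobulin constant regions diverged, with Igha from 8.10 ± 0.979 to 35.2 ± 4.21 CPM and Ighg1, of IgG1, from 492 ± 13.9 to 180.2 ± 6.38 CPM. Heat shock genes rose for 8 of 11, with Dnajb1 at 1.24 ± 0.07 (camera, adjusted p = 7.06e-21), and took 1.98 ± 0.0256 % of reads against 1.48 ± 0.0265 % (SD, n = 3). The TNF and NF-kB list rose for 11 of 17, with Nfkbia at 0.86 ± 0.07 (camera, adjusted p = 2.1e-08). Interferon gamma response genes fell for 8 and rose for 2 of 19, with the guanylate-binding protein Gbp3 at -0.72 ± 0.05 (camera, adjusted p = 0.00676, and adjusted p = 0.102 with an estimated correlation). The TGF-beta list rose for 6 and fell for 1 of 11 (6 and 2 adjusted over the list alone; camera, adjusted p = 0.000292, and adjusted p = 0.0533 with an estimated correlation). T cell markers fell beside these for 11 and rose for 1 of 16 (12 and 1 adjusted over the list alone), with Thy1 at -2.08 ± 0.18 (camera, adjusted p = 6.67e-08). Stromal markers fell for 7 of 8, with Col3a1 from 49.4 ± 4.06 to 0.940 ± 0.546 CPM (camera, adjusted p = 1.11e-35). Of 13608 genes tested 2872 passed, 1498 higher and 1374 lower (1318 and 1545 with upper-quartile scaling), with 219 up and 324 down at least 2-fold.

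**Figure D3:**
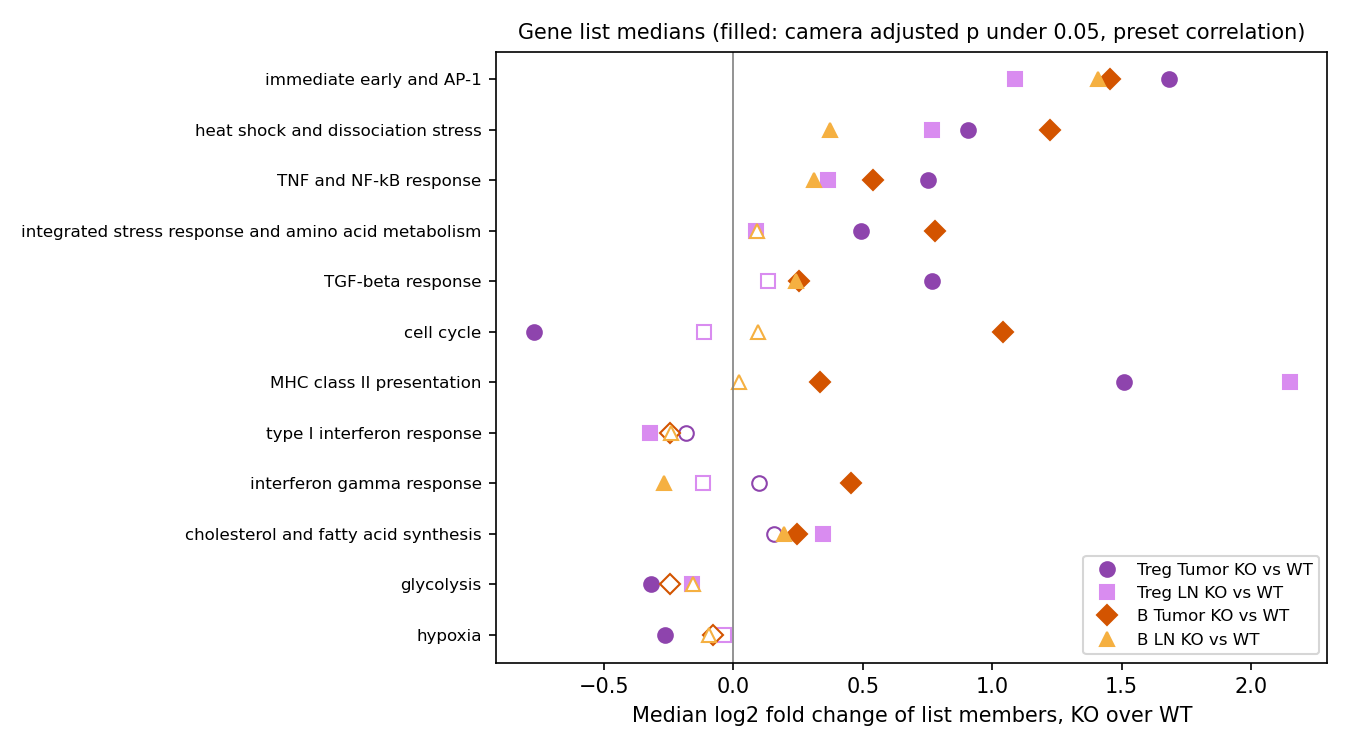
Median log2 fold change (libraries labelled KO over WT) of the members of 12 gene lists in the 4 genotype comparisons. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation; immediate early genes have medians from 1.09 to 1.68.

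Tumour and lymph node were then compared within the libraries labelled WT, to describe tumour Tregs of mice labelled as controls. The suppressive mediator Fgl2 rose from 71.7 ± 5.40 CPM in lymph node to 445 ± 27.8 CPM in tumour (SD, n = 3), a change of 2.64 ± 0.06 (edgeR, adjusted p = 1.2e-26). Gzmb changed by 2.18 ± 0.06, Pdcd1 by 2.16 ± 0.06, Tnfrsf9, the receptor 4-1BB, by 1.97 ± 0.06, and Ctla4 by 1.08 ± 0.04. Foxp3 rose by 0.41 ± 0.05 and Appl2 by 1.28 ± 0.10 (edgeR, adjusted p = 3.7e-12). In all, 5993 of 14504 genes tested passed, 3105 higher and 2888 lower in tumour (2961 and 3082 with upper-quartile scaling), with 1173 up and 720 down at least 2-fold.

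Effector Treg genes were higher in tumour for 17 and lower for 5 of 25 (camera, adjusted p = 2.95e-15). Naive and central T cell genes were lower for 15 and higher for 1 of 16, with Tcf7 at -2.38 ± 0.07 and Il6ra at -2.68 ± 0.09 (camera, adjusted p = 1.12e-40). Glycolysis genes were higher for 16 of 17, with Tpi1 at 2.16 ± 0.06 and Aldoa at 1.93 ± 0.05 (camera, adjusted p = 1.04e-42), and hypoxia genes were higher for 15 of 16, with Bnip3 at 3.35 ± 0.11 (camera, adjusted p = 3.34e-16). Cholesterol and fatty acid synthesis genes were higher for 16 of 22 (16 higher and 2 lower adjusted over the list alone), with Hmgcs1 at 1.77 ± 0.09 (camera, adjusted p = 2.63e-07). The TNF and NF-kB list was higher for 13 and lower for 2 of 19, and the interferon gamma list for 13 and 2 of 20 (camera, adjusted p = 1.73e-11 and 2.14e-07). All 11 melanoma markers were higher in tumour, with Trpm1 at 3.87 ± 0.15 and a list median of 5.76, or 5.54 with S100b at its bound (camera, adjusted p = 2.18e-37). Whether melanoma RNA in these libraries adds to the rise of glycolysis and hypoxia genes was not tested. Erythroid markers were higher for 5 of 6 and all 11 B cell markers were lower, with Pax5 at -4.37 ± 0.28 (camera, adjusted p = 7.73e-18 and 2.65e-11). CD8 T and NK cell markers were higher for 7 of 8 (8 adjusted over the list alone), with Klrk1 at 2.55 ± 0.39 (camera, adjusted p = 0.0085, and adjusted p = 0.236 with an estimated correlation). Stromal and endothelial markers were lower for all 11, with Col4a1 at -1.50 ± 0.09 (camera, adjusted p = 6.04e-09, and adjusted p = 0.0538 with an estimated correlation). Dct had 27.1 ± 26.4 CPM in the lymph node libraries (SD, n = 3), a spread as large as its mean, so no fold is given for it.

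In B cells labelled WT, the plasma cell list was higher and the cell cycle list lower in tumour than in lymph node, while single immunoglobulin genes went both ways. Igha rose from 8.35 ± 0.997 to 785 ± 71.8 CPM (SD, n = 3), a change of 6.56 ± 0.09 (edgeR, adjusted p = 4.5e-19), and Jchain from 58.9 ± 4.42 to 798 ± 121 CPM. Ighg2c rose from 55.5 ± 1.65 to 852 ± 55.2 CPM, while Ighg1 changed by -2.03 ± 0.06. Mki67 fell from 651 ± 26.3 to 165 ± 3.88 CPM, and Mybl1, a transcription factor of germinal centre B cells, changed by -3.81 ± 0.18. Plasma cell genes were higher in tumour for 16 and lower for 2 of 21 (camera, adjusted p = 1.89e-20). Germinal centre genes were lower for 12 and higher for 1 of 14 (13 and 1 adjusted over the list alone; camera, adjusted p = 5.57e-16). Cell cycle genes were lower for 29 of 33 (31 adjusted over the list alone; camera, adjusted p = 1.96e-30). B cell identity genes were lower for 9 and higher for 2 of 18 (10 and 3 adjusted over the list alone), with the complement receptor Cr2 at -1.06 ± 0.05 (camera, adjusted p = 0.000221). MHC class II genes were lower for 9 and higher for 1 of 12, with the transactivator Ciita at -1.12 ± 0.05 (camera, adjusted p = 0.000274, and adjusted p = 0.0824 with an estimated correlation). Immediate early genes were higher for 19 and lower for 2 of 25 (20 and 2 adjusted over the list alone), with Jun at 1.81 ± 0.05 (camera, adjusted p = 4.8e-17). Heat shock genes were higher for 6 and lower for 1 of 11 (7 and 1 adjusted over the list alone; camera, adjusted p = 9.37e-18). Hspa1b was at 2.47 ± 0.05, though its reads are hard to tell from those of its near-identical copy Hspa1a. Hypoxia genes were higher for 11 and lower for 1 of 16 and the TNF and NF-kB list for 14 and 1 of 19 (11 and 1, and 14 and 2, adjusted over the list alone; camera, adjusted p = 2.44e-06 and 1.27e-10).

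Other cells' transcripts accompanied these changes in B cells labelled WT. Macrophage and monocyte markers were higher in tumour for all 12, with Lyz2 at 2.48 ± 0.09 (camera, adjusted p = 2.17e-19). So were all 9 melanoma markers, with Dct from 9.62 ± 2.81 to 696 ± 49.7 CPM (camera, adjusted p = 8.82e-35). Whether melanoma RNA adds to the rise of hypoxia genes in these B cell libraries was not tested. All 6 erythroid and platelet markers were higher, with Hbb-bs at 7.01 ± 0.17 and a list median of 7.28, or 6.92 with Hba-a2 and Pf4 at their bounds (camera, adjusted p = 1.78e-54). T cell markers were lower for 10 and higher for 1 of 16, with Thy1 at -1.49 ± 0.21 (camera, adjusted p = 0.00192, and adjusted p = 0.0924 with an estimated correlation). Hba-a2, a haemoglobin gene with a near-identical copy, had 0 reads in the lymph node libraries and was at least 366-fold higher in tumour. Appl2 rose by 0.96 ± 0.12 (edgeR, adjusted p = 7.1e-06), and 4141 of 13770 genes tested passed, 2167 higher and 1974 lower in tumour, with 922 up and 334 down at least 2-fold.

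Whether the KO effect differed between tumour and lymph node was tested by an interaction term over the 12 libraries of each cell type. In Tregs, whose lymph node arm follows labels that Appl2 did not bear out, the effect on Foxp3 differed by -0.64 ± 0.06. Cell cycle genes differed downward there for 24 and upward for 2 of 33, with a median of -0.68 (camera, adjusted p = 1.11e-16). In B cells, cell cycle genes differed upward for 22 of 33 (26 adjusted over the list alone) with a median of 0.99 (camera, adjusted p = 1.61e-15). Germinal centre genes differed upward for 9 and downward for 1 of 14 (10 and 1 adjusted over the list alone; camera, adjusted p = 2.08e-08). Markers of other cells differed beside these. In Tregs melanoma markers differed downward for 8 of 11, B cell markers upward for 7 of 14 (8 adjusted over the list alone) and stromal markers upward for 9 of 11 (camera, adjusted p = 3.41e-10, 0.000647 and 2.19e-05). In B cells T cell markers differed upward for 13 of 16, CD8 T and NK cell markers upward for 5 of 9 and macrophage markers downward for 5 of 12 (7 adjusted over the list alone; camera, adjusted p = 9.54e-31, 4.31e-05 and 1.05e-07). Heat shock genes differed upward there for 7 and downward for 2 of 11 (camera, adjusted p = 4.57e-17). For the immediate early genes the term passed in Tregs, with a median of 0.43 (camera, adjusted p = 5.93e-13), and not in B cells, with a median of 0.13 (camera, adjusted p = 0.0849). In Tregs 5319 of 15589 genes tested had a differing effect, 2615 upward and 2704 downward, and in B cells 3086 of 14737, 1826 upward and 1260 downward (1580 and 1533 with upper-quartile scaling).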

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

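The test of an action inside Foxp3-expressing cells alone and the splits that keep every tumour label were chosen only after the results they bear on had been seen. A first pattern was the rise of immediate early genes in the libraries labelled KO in all 4 genotype comparisons, by a list median of 1.68 ± 0.20 in tumour Tregs, 1.09 ± 0.17 in lymph node Tregs, 1.45 ± 0.23 in tumour B cells and 1.41 ± 0.13 in lymph node B cells (± standard error over members). RNA of the other lymphocyte in the gates is argued against, since the median was 1.41 in lymph node B cells, where T cell markers had a median of -2.16. An action of the deletion inside Foxp3-expressing cells alone is argued against by the rise in B cells, which is itself part of the pattern. The mean difference Treg minus B over members was 0.165 ± 0.174 in tumour, and -0.284 ± 0.118 in lymph node, where Appl2 was not lower in Tregs labelled KO. A general heat shock or dissociation stress of the libraries labelled KO remains open, with heat shock medians above 0 in all 4 comparisons and the lowest at 0.373 ± 0.209 in lymph node B cells, and the mitochondrial share of reads was lower in the libraries labelled KO in all 4. An indirect effect of the genotype stays open too and was not tested. A candidate explanation is therefore a difference in stress or handling between the mice or cells of the 2 genotype labels, in life or during sorting, which these libraries hold no means to separate.

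A second pattern was Appl2 itself, which was lower in B cells labelled KO and not lower in lymph node Tregs labelled KO. Foxp3-driven recombination is not meant to act in B cells. Foxp3 averaged 7.96 to 10.9 CPM in the B cell groups, but other genes cover 31.5 % of its exon bases. The B cell groups also held T cell RNA, at 0.499 to 5.28 % by markers. In tumour, Foxp3 was at 8.17 CPM with a share of 5.28 % (KO) and at 10.3 CPM with 0.670 % (WT). It thus did not follow the share there. In lymph node the lower level, 7.96 CPM (KO), went with the lower share, 0.499 %, and 10.9 CPM (WT) with 1.86 %. The origin of the Foxp3 reads was not tested. B cell RNA in the lymph node Treg gate could bring only 0.592 CPM of Appl2. That is 3.70 % of the 16.0 CPM by which Appl2 exceeded the level scaled from tumour Tregs, so this source is argued against. The scaling takes the tumour ratio as the expected fall. Appl2 in tumour Tregs labelled KO, at 24.6 CPM, was near both lymph node Treg groups, at 26.2 (KO) and 22.2 CPM (WT). Tumour Tregs labelled WT stood apart at 53.7 CPM, in libraries that also held melanoma transcripts. What set Appl2 higher there was not tested. An exchange of KO and WT labels among the lymph node Treg libraries is argued against by the direction of 1219 genes called in 1 direction in the other 3 genotype comparisons, of which 90.6 % had the same sign in lymph node Tregs. Recombination outside Foxp3-expressing cells may account for the change of -1.08 ± 0.13 in lymph node B cells, and stays open because gene totals hold no exon counts. No biological explanation for the lymph node Treg level was tested.

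The last pattern was the abundance of melanoma transcripts in the tumour libraries labelled WT and their fall in those labelled KO. Melanoma cells or their free RNA in the sorted WT libraries stay open as a source. The levels of 11 melanoma markers went together in tumour Tregs and B cells labelled WT (Pearson r = 0.988 across genes, which are not independent replicates). The markers spread from 1.69 to 11.2 in log2 CPM in these Tregs, and such differences in abundance alone raise r. The value therefore cannot tell sources apart. The most abundant, Dct, averaged 2345 CPM in tumour Tregs and 659 CPM in tumour B cells labelled WT, scaled over all 24 libraries. Sorting on lymphocyte markers should remove melanoma cells. A difference in tumour size or in the sort between genotype labels may underlie the pattern and was not tested.

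Regrouping the libraries was tested as well. For each of the 6 pairwise comparisons the 10 possible splits are too few for a share under 0.05, with real counts of 7869, 3689, 5410, 2872, 5993 and 4141 genes in tumour Tregs, lymph node Tregs, tumour B cells, lymph node B cells, and the tissue comparisons of Tregs and B cells, where the highest other split gave 0. In Tregs, of 100 splits drawn from 200 for the interaction only the real 1 reached 5319 genes, and the highest other gave 5253. That share is under 0.05 for a regrouping of both tissues at once, but it speaks of the tumour labels alone. Drawn splits that changed these labels gave at most 49 genes, while those that kept them gave 3961 to 5253. The count therefore cannot exclude chance for a difference of the KO effect between tissues. In B cells 5 of 100 splits, the real one included, reached 3086 genes, and the highest other gave 3542, so chance could not be excluded for that count. All of these kept every tumour label, and drawn splits that changed tumour labels gave at most 25 genes. For the lymph node labels alone, the 20 splits that keep every tumour label are too few for a share under 0.05. The real count was reached by 2 of the 20 in Tregs and by 11 in B cells, the real split included. The highest other, with lymph node labels exchanged, gave 7840 genes in Tregs and 5916 in B cells.

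The following results were set apart because the KO effect in tumour differed from that in lymph node by the interaction test, given as log2 differences and, in the lymph node arm of Tregs, by labels that Appl2 did not bear out. In Tregs 5319 genes differed, Appl2 by -1.36 and Foxp3 by -0.64. Ighg1 differed by 11.06, with 2 reads in tumour Tregs labelled WT, both in replicate 3, against 1391 in those labelled KO, so its size is uncertain. Ighg2b differed by 7.31, Ighg2c by 6.54 and Iglc1 by 6.09 (7.37 without tumour Treg WT replicate 1), like Ighg1 immunoglobulin genes with close copies. The small nucleolar RNA Snord3b4 differed by 5.17. Tyr differed by -6.60, which rests on lymph node libraries with few reads, as it was -7.26 without lymph node Treg KO replicate 1, -8.62 without lymph node Treg WT replicate 3 and -7.93 without tumour Treg KO replicate 1, and without lymph node Treg KO replicate 3, which holds all reads of its group, it did not pass (edgeR, adjusted p = 0.885, from 1.4e-09 over its alternatives). Kif21a differed by -5.90 (-6.64 without lymph node Treg WT replicate 2 and -7.21 without tumour Treg KO replicate 3). Mlph differed by -5.45 (-4.70 without lymph node Treg KO replicate 2 and -6.67 without lymph node Treg WT replicate 3). Syt4 differed by -5.43 (-6.85 without lymph node Treg WT replicate 1 and -7.48 without tumour Treg KO replicate 3) and Met by -5.26 (-4.60 without lymph node Treg KO replicate 1).

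By list medians, the Treg effect differed by -0.28 for Treg identity, 0.59 for naive and central T cell genes, 0.14 for the TNF and NF-kB response, 0.43 for immediate early genes, 0.67 for the TGF-beta response, and -0.68 for cell cycle. It differed by 1.47 for B cell markers (1.25 with Cr2 at its bound), and -5.16 for melanoma markers (-5.21 with Slc45a2, Oca2 and S100b at their bounds). For stromal markers it differed by 1.99, also with Dcn and Pdgfrb at their bounds. Calls lost under an estimated correlation were CD8 T and NK cell markers at 1.38, or 1.78 with Gzmk, Ncr1 and Klra7 at their bounds (camera, adjusted p = 0.0768 with an estimated correlation), glycolysis at -0.26 (adjusted p = 0.259 with an estimated correlation), hypoxia at -0.27 (adjusted p = 0.101 with an estimated correlation) and the integrated stress response at 0.32 (adjusted p = 0.137 with an estimated correlation). MHC class II at -0.41 (camera, adjusted p = 0.141 with an estimated correlation) also lost its call without lymph node Treg WT replicate 1, tumour Treg KO replicate 3 or tumour Treg WT replicate 3 (adjusted p = 0.0538, 0.0710 and 0.0522). Oxidative phosphorylation at 0.19 (camera, adjusted p = 0.378 with an estimated correlation) lost it without lymph node Treg KO replicate 2, lymph node Treg WT replicate 3, tumour Treg KO replicate 2 or tumour Treg WT replicate 3 (adjusted p = 0.0506, 0.0987, 0.0798 and 0.0569). Chemokine receptors at 0.16 (camera, adjusted p = 0.101 with an estimated correlation) lost it without lymph node Treg KO replicate 2 or 3, lymph node Treg WT replicate 2 or tumour Treg WT replicate 3 (adjusted p = 0.0506, 0.0548, 0.0684 and 0.0526).

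In B cells 3086 genes had an effect that differed between tissues by the same test. The T cell genes Cd8b1, Bcl11b, Cd3g and Thy1 differed by 6.08, 5.76, 5.51 (6.37 for Cd3g without lymph node B cell KO replicate 3) and 5.33. Hba-a2, with 0 reads in lymph node B cells labelled WT, had a fitted difference of -6.33 that depends on the prior count, or -3.51 with that group at the floor of 3 counts. Hbb-bt differed by -3.32, with all 4 reads of lymph node B cells labelled WT in replicate 1, and did not pass without lymph node B cell KO replicate 1 (-2.93; edgeR, adjusted p = 0.0740) or WT replicate 2 (-2.76, adjusted p = 0.0507, from 2.8e-05 over its alternatives). Igha differed by -4.26, Il1b by -3.50 and Magi1 by -2.97. List medians differed by 4.96 for T cell markers, 4.75 for CD8 T and NK cell markers (2.79 with Gzmk and Klrb1c at their bounds), -2.08 for macrophage markers, 0.98 for heat shock, 0.99 for cell cycle, 1.42 for germinal centre, 0.25 for B cell activation, 0.47 for interferon gamma, 0.076 for TNF and NF-kB and 0.61 for the integrated stress response. Those for plasma cell genes at 0.34 (camera, adjusted p = 0.225 with an estimated correlation) and MHC class II at 0.31 (adjusted p = 0.107 with an estimated correlation) lost their calls.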

How the results depend on the processing

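The 3 alternatives chosen after seeing the data were a minimum fold of 2, leaving out genes of other cells, and leaving out a pair of tumour B libraries; the rest were planned. In the order tumour Tregs, lymph node Tregs, tumour B cells, lymph node B cells, tissue in Tregs, tissue in B cells, and the interactions of Tregs and B cells, requiring at least 2-fold left 2588, 863, 1900, 543, 1893, 1256, 1561 and 991 genes, fewer by construction. Without genes of other cells the counts were 7410, 3304, 5073, 2713, 5638, 3778, 5035 and 2898, and with DESeq2 7373, 3245, 5166, 2512, 5474, 3816, 5230 and 3180, all within 1.5 times the reported counts. Replicate numbers do not pair the libraries (correlation of same-number differences -0.019 to 0.019), and a block on that number gave 7705, 3523, 5164, 2830, 5817, 4236, 5053 and 2908. Without tumour B cell WT replicate 2 and KO replicate 1, whose pairs within their groups differed most (chi-square per gene 7.89 to 11.5), the B cell counts were 5748 in tumour, 4480 between tissues and 3747 for the interaction. Leaving out each library gave 7304 to 7576, 2888 to 3776, 4405 to 5403, 2217 to 2831, 5319 to 5727, 3163 to 4480, 4879 to 5265 and 2521 to 3570 genes. The larger side of the counts depended on scaling, since with upper-quartile factors fewer genes were higher than lower in all 4 genotype comparisons (3591 and 4339, 1808 and 2105, 2482 and 3053, 1318 and 1545) and between tissues in Tregs (2961 and 3082). In the B cell interaction the upward excess shrank to 1580 against 1533. In tumour B cells the larger side also turned with all 4 groups in 1 fit (3226 and 3292), and between tissues in Tregs with no filter (3134 and 3240). In the Treg interaction it turned with DESeq2 (2694 and 2536), RLE factors (2741 and 2605) and without genes of other cells (2519 and 2516). In tumour Tregs, where the sides were near equal, it turned under several alternatives, among them without KO replicate 3 (3766 and 3810). Of the values for named genes 10067 kept direction and side of the threshold under an alternative, 173 became weaker, 6 stronger and 8 reversed; of those for lists 1501 kept and 75 became weaker, 42 of them under an estimated correlation. The reversals were of values near 0 that never passed. Ddx3y in tumour Tregs was 0.01, and -0.041 with upper-quartile factors, -0.015 under the stricter filter and -0.052 to 0.055 leaving out a library. Eif2s3y in tumour B cells was -0.00, and 0.00285 with no filter and -0.058 to 0.094 leaving out a library; the cause was not tested. The stricter filter, which tests fewer genes, ended the list calls of hypoxia (adjusted p = 0.0893) and apoptosis regulators (0.0705) in tumour Tregs, glycolysis in lymph node Tregs (0.0543), MHC class II and interferon gamma (0.110 each) and cholesterol synthesis (0.0784) in tumour B cells, and regulatory B cell genes in lymph node B cells (0.0927), all by camera with Benjamini-Hochberg adjustment. It also ended that of chemokine receptors between tissues in B cells (0.0627), which was lost without tumour B cell WT replicate 1 too (0.0734), and those of MHC class II (0.0859), oxidative phosphorylation (0.109) and chemokine receptors (0.0624) in the Treg interaction. Upper-quartile factors ended MHC class II and interferon gamma in tumour B cells (0.0504 each), and the block ended hypoxia in tumour Tregs (0.0512) and chemokine receptors in the Treg interaction (0.0600). Without 1 library hypoxia in tumour Tregs (KO replicate 2, KO replicate 3 or WT replicate 1; 0.0519, 0.0698 and 0.0545) and glycolysis in lymph node Tregs (KO replicate 1, KO replicate 3 or WT replicate 3; 0.0546, 0.0751 and 0.0531) lost their calls. On simulated counts 26 to 72 % of genes changed 1.5-fold were recovered, so changes of that size are missed at this depth and spread between libraries. Depth leaves genes with 0 reads in a group, such as Hba-a2 in lymph node B cells labelled WT, with a bound alone.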

Other observations

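The overlap of genes across comparisons and the share of calls open to other lymphocytes' RNA were computed only after the results they rest on had been seen. Genes in and outside the fixed lists moved together across cell types and tissues. Of 12099 genes tested in all 4 genotype comparisons, which share no libraries, 547 were higher in the libraries labelled KO in each and 223 lower. Of these 475 and 207 lay outside the fixed lists. Independent comparisons would give 13.8 and 6.28. Independence is not given, since the cells may come from the same mice and a difference in handling between genotype labels would be shared. The 2 expected numbers are therefore a reference and not a test. Beside Fosb, those higher in each included the nicotinic receptor subunit Chrna2 (1.96, 2.55, 2.01 and 1.73 in tumour Tregs, lymph node Tregs, tumour B cells and lymph node B cells), the transcriptional regulator Sertad1 (2.81, 1.64, 2.46 and 1.56) and the microRNA host transcript Mir22hg (1.78, 1.53, 2.72 and 1.42). Genes lower in each included Sparcl1, an extracellular matrix protein of vessels and stroma (-5.55, -3.68, -5.45 and -4.35), complement C4b (-4.02, -3.03, -4.07 and -3.14) and Fkbp5, a chaperone of the glucocorticoid receptor that glucocorticoids induce (-1.33, -1.05, -2.42 and -1.95). The names in this paragraph were chosen after their values were seen, and the lymph node Treg values follow labels that Appl2 did not bear out.

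In lymph node Tregs by the same labels, fatty acid oxidation genes fell for 4 of 17 (5 adjusted over the list alone), with the transporter Fabp4 at -3.52 ± 0.19 and Cpt1a at -0.52 ± 0.07 (camera, adjusted p = 0.00323, and adjusted p = 0.232 with an estimated correlation). In tumour Tregs labelled WT against lymph node, helper T cell genes included Tbx21 at 3.18 ± 0.20 (camera, adjusted p = 0.0035, and adjusted p = 0.0616 with an estimated correlation), and Itgae, an integrin of tissue-resident T cells, changed by -1.49 ± 0.05. In B cells labelled WT, the chemokine receptor Ccr2 rose by 4.66 ± 0.26 in tumour and glycolysis genes rose for 12 of 17 (15 adjusted over the list alone; camera, adjusted p = 0.000844, and adjusted p = 0.137 with an estimated correlation). Early endosome and Rab trafficking genes, among which Appl2 acts, passed as a list in none of the 6 pairwise comparisons or the interactions, with a median of -0.15 in tumour Tregs (camera, adjusted p = 0.382). Appl1, the closest relative of Appl2, changed by -0.33 ± 0.06 in tumour Tregs labelled KO (edgeR, adjusted p = 1.3e-05).

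The share of called genes to which RNA of the other lymphocyte would bring most of the change was computed from the shares of T or B cell RNA. It was 263 of 2010 genes higher in lymph node Tregs labelled KO (13.1 %), 33 of 3944 in tumour Tregs (0.837 %), 135 of 2871 in tumour B cells (4.70 %) and, for genes lower, 31 of 1374 in lymph node B cells (2.26 %). The estimate rests on B cell markers in Treg libraries and on T cell markers in B cell libraries, with Tregs as the T cell reference. It does not cover antibody-secreting cells, melanoma cells or, in Treg libraries, CD8 T and NK cells. In tumour Tregs Cd8b1 stood at 101 ± 3.92 CPM labelled KO and 15.4 ± 1.42 CPM labelled WT, and Dct at 36.3 ± 2.13 and 2345 ± 85.9 CPM. The shares are therefore not those of all other cells' RNA. In tumour Tregs labelled KO, with a B cell share of 1.46 %, Igkc stood at 489 ± 13.2 CPM, against 1608 ± 31.3 CPM in tumour B cells labelled KO (SD, n = 3). Xist was near 0 in every group, at most 0.429 CPM on average, and the Y-linked gene Ddx3y was read in all groups, between 126 and 271 CPM. Scaled over all 24 libraries, the melanoma gene Dct was also read in lymph nodes, at 25.6 ± 24.8 CPM in Tregs and 9.54 ± 2.78 CPM in B cells labelled WT, against 13.1 ± 0.316 and 0.223 ± 0.0909 CPM in those labelled KO (SD, n = 3).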
